A study of Naumovozyma castellii with 6 samples.

How the data were processed

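The series measured messenger RNA in 6 libraries of Saccharomyces (now Naumovozyma) castellii. They came from the wild type strain DPB005, the ago1 deletion strain DPB007 and the dcr1 deletion strain DPB009, with 2 replicates per strain that the labels call biological. Cells were grown in YPD at 25 °C to an OD600 of 0.6 to 0.8. Per the labels, RNA was extracted with hot phenol, treated with DNase, selected with oligo-dT, broken by alkaline hydrolysis and sized to 25 to 45 nt, and adaptors were ligated to the RNA fragments themselves, so that reads keep the strand. The deposited files give, for each distinct read sequence of 36 nt, its number of reads, and the authors' values are therefore raw counts. Identical reads had been collapsed, the 3' adaptor had not been removed, and the files name no gene and no genome position. The aligner, genome build and filters behind the authors' own analysis are not given in the sources used here.

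No genome sequence of this species was used here, and none of the 5867 genes in the reference table could be linked to the files by an identifier (0 matched). Reads were therefore assembled into transcript segments, and segments take the place of genes in every test. Reads were trimmed of the 3' adaptor (21 nt of it were searched), and trimmed reads under 22 nt, or with at least 80% A, were left out. Each distinct read counted once per library in the assembly, which followed words of 19, 21, 23 and 27 nt in turn on the strand as read. Words seen under 2 times and branches under 35% of the stronger branch were dropped, and segment ends with a single overlap of at least 13 nt were joined. Segments of at least 100 nt were kept, which gave 18265 segments with a total length of 6158737 nt and an N50 of 516 nt. Reads were placed on the segments with at most 1 mismatch, with the first or last 11 nt as the seed, and reads with 1 best place were counted on the sense strand. Reads that matched the opposite strand of a segment at least as well as any sense place were counted apart as its antisense reads, and these can at the same time be sense reads of an overlapping segment. A gene can be split over several segments, so a count of segments is not a count of genes.

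Gene names rest on matches of the translated segments (blastx, BLAST 2.17.0, E-value up to 1e-06) to 94 protein sequences written by hand from background knowledge, chosen after the read files had been seen to hold no gene names. A housekeeping name needed at least 60% identity, so a name states the closest of the proteins searched and not a proven ortholog. AGO1, retrotransposon proteins, Y' type helicases, cell wall proteins and drug-resistance markers were named at any identity, because these diverge fast between species. RNT1 needed at least 40% identity. The name DCR1 was given by the catalytic signature of RNase III proteins. In all, 371 segments were named, and 91 of the 94 proteins had at least 1 segment. The E-value limit was fixed at 1e-06, and 1e-05 was tried as an alternative after counts had been seen. Mitochondrial ribosomal RNA was named by conserved sequence motifs. Segments of at least 200 nt under 25% GC, or named as mitochondrial, were called AT-rich. The 119 segments of cytosolic ribosomal RNA were left out of the tests and the library sizes.

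Tests used edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, two-sided) in R 4.3.3 on all 6 libraries together, with 1 mean per strain and no other term. A segment was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15230 segments tested. Fitted log2 fold changes are given with their standard error, and CPM are counts scaled to a total of 1e6 after TMM scaling. Where 1 group held 0 counts, a fold is a lower bound against a floor of 3 counts over the group's 2 libraries together. With 1 to 3 counts the ratio is given with its 95% exact binomial interval. These intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Antisense counts were tested the same way with the scaling of the sense counts. Reads of 6 repeat families (Ty1/copia type, Ty3/gypsy type and Y' type helicase, each by coding and opposite strand) were summed per family and tested in the same fit, adjusted over the 6 families. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. A list under 3 tested segments was described by its values. The response shared by both deletions was compared with 1000 simulations of unchanged groups that keep the same wild type controls. The wild type group has too few libraries to be split between the comparisons.

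The comparisons, tests, gene lists and the rule for named segments were chosen before the data were examined, with genes in mind, and segments then took their place. The members tested were limited to the proteins searched, which were chosen later. Planned lists with no protein searched were not run. Among them were general stress, phosphate, iron and copper, mating, meiosis, silencing and telomeres, RNA decay and cell cycle genes. The rule names AGO1 and DCR1, then up to 10 segments that rose and 10 that fell with the largest fitted change among those called, with a mean of at least 20 counts in the higher group and both deletion libraries on the same side of both wild type libraries. It adds up to 4 members with the smallest p per list, each repeat family, and the 5 with the smallest adjusted p in each direction for the comparison of the deletions and for antisense counts. Sets of AT-rich segments and of segments overlapping a segment of the other strand by at least 100 nt were added after the data had been seen. An overlap is any match of at least 95% identity to the opposite strand of another segment. Diverged copies from different places can therefore count as overlapping.

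Alternatives were upper quartile scaling, DESeq2 1.42.0, no filter, a filter of at least 50 counts in 2 libraries, a replicate block, reads without mismatch only, reads with several places shared, distinct tags, a correction for GC content and length with and without the block, only the groups compared, and leaving out each library in turn. Leaving out the segments of AGO1, DCR1 and the markers was added later. Where a library is left out its group keeps a lone library, which is assumed to vary like the other groups. Tests of subtelomeric genes, of convergent genes, of gene families near chromosome ends and of distances on the genome need genome positions and were not run. No inverted repeat was found within a segment (0 found). Assembly, placement and tests were tested on simulated data. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.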

Results

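Messenger RNA was sequenced from 3 strains of Saccharomyces (Naumovozyma) castellii, a budding yeast that has RNA interference. They were the wild type, a strain lacking AGO1, which encodes the Argonaute protein that binds small interfering RNAs, and a strain lacking DCR1, which encodes the Dicer enzyme that makes them. Each strain had 2 libraries, and the series title names the effect of RNA interference on the transcriptome as the question. The libraries held 5237134 to 5873485 reads, of which 69.7% to 76.3% were placed on transcript segments assembled from the reads themselves, and cytosolic ribosomal RNA took 10% to 13.9% of the reads. The counts behind the tests came to 3115429 and 3560439 in the wild type, 3204804 and 3571163 in the ago1 deletion, and 3503553 and 3701807 in the dcr1 deletion. Errors of log2 fold changes of a segment or family are standard errors of the fit (n = 2 libraries per strain). Errors of medians over a set are taken across its segments, which are not independent replicates, and leave out variation between libraries.

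Replicates lay closest in the wild type and farthest apart in the ago1 deletion. The variance between the 2 libraries of a strain, relative to counting error, was 1.64 in the wild type, 10.9 in the ago1 deletion and 2.91 in the dcr1 deletion. Pearson's r between replicates was 0.979, 0.955 and 0.976 in that order, across segments, which are not independent replicates. In ago1 deletion replicate 1, reads made mostly of A were 1.88% of the reads against 0.203% to 0.410% in the other 5 libraries, and distinct sequences were 54.0% of the reads against 59.4% to 69.3%.

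AGO1 was nearly absent from the ago1 deletion, and DCR1 was not detected in the dcr1 deletion. The 3 segments matched to AGO1 (seg05167, seg07578 and seg15291, 33.3% to 48.6% identity over 35 to 96 amino acids) held 106 and 129 counts in the wild type, 1 and 0 in the ago1 deletion, and 114 and 146 in the dcr1 deletion. The wild type level was 202 times that of the ago1 deletion (95% interval 36 to 8031). The segment carrying the RNase III signature of DCR1 (seg17788) held 7 and 11 counts in the wild type, 7 and 13 in the ago1 deletion, and 0 and 0 in the dcr1 deletion, at least 6.12-fold lower than the wild type against a floor of 3 counts over the group, and this did not pass the test over all segments (adjusted p = 0.0659). This test passed without ago1 deletion replicate 1 (adjusted p = 0.00511) and replicate 2 (adjusted p = 0.005), and not without wild type replicate 1 (adjusted p = 0.269) or replicate 2 (adjusted p = 0.861) or dcr1 deletion replicate 1 (adjusted p = 0.337) or replicate 2 (adjusted p = 0.812). It also passed with no filter on low counts (adjusted p = 0.0336), distinct tags (adjusted p = 0.0297), the replicate block (adjusted p = 0.037) and the block with the correction for GC content and length (adjusted p = 0.0341), and not by DESeq2 (adjusted p = 0.179). RNT1, the other RNase III gene of yeasts, held 287 and 328 counts in the wild type, 235 and 365 in the ago1 deletion, and 357 and 448 in the dcr1 deletion. Reads of a hygromycin-resistance gene were at 2386 and 2314 in the ago1 deletion, and 0 and 0 in the wild type. Reads of a kanamycin-resistance gene were at 7992 and 10082 in the dcr1 deletion, 53 and 136 in the ago1 deletion, and 1 and 0 in the wild type. The most frequent read of the AGO1 segment seg05167, ATGTGCAGAAGATATAAACTTACTGAA, was seen 1 and 2 times in the wild type and 0 times in the ago1 deletion.

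**Figure D1:**
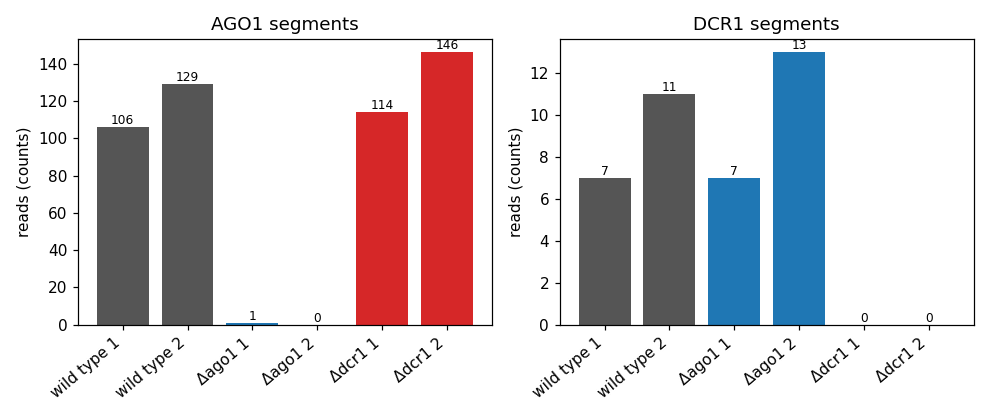
Bars show reads per library (counts) on the segments matched to AGO1 and to DCR1, for the 2 libraries of each strain, with the count printed on each bar. AGO1 stands at 1 and 0 counts in the ago1 deletion and DCR1 at 0 and 0 in the dcr1 deletion.

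In the ago1 deletion 14 of 15230 segments rose and 19 fell. Beyond the markers, the segments that rose were a short segment resembling the cell wall mannoprotein TIR1 (seg10820, 45.5% identity over 33 amino acids, log2 fold change 2.0 ± 0.31, adjusted p = 0.00443) and the cytochrome c1 gene CYT1 of the respiratory chain (seg04544, 1.30 ± 0.26, adjusted p = 0.043). Unnamed segments that rose by the naming rule were seg13811 (2.0 ± 0.36), seg06983 (1.81 ± 0.21), seg02545 (1.26 ± 0.18), seg06026 (1.24 ± 0.19), seg10176 (1.22 ± 0.24) and seg04405 (1.14 ± 0.20). URA1 of pyrimidine synthesis also rose (seg00944, 0.86 ± 0.17, adjusted p = 0.046), with 184 and 153 CPM against 96.2 and 89.3 in the wild type. Among the segments that fell, 9 unnamed ones were at 3 counts or fewer over both ago1 deletion libraries, besides the 3 of AGO1. They include seg05028 (at least 25.0-fold lower), seg09846 (at least 20.1-fold), seg08395 (at least 17.5-fold), seg09158 (at least 16.1-fold) and seg08651 (at least 11.5-fold), each bound against 3 counts over the group. The others that fell by the rule were seg06319 (−3.87 ± 0.48), seg15343 (−2.13 ± 0.36) and seg03847 (−1.79 ± 0.35).

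The count in the ago1 deletion rests on single libraries. It was 15 without wild type replicate 1, 10 without wild type replicate 2, 111 without ago1 deletion replicate 1, 2057 without ago1 deletion replicate 2, 19 without dcr1 deletion replicate 1 and 18 without dcr1 deletion replicate 2. Of the 10 named segments that rose, only the 2 markers kept their call without any single library, and 8 of the 14 named segments that fell did, among them seg05167 and seg07578 of AGO1. CYT1 lost its call without either wild type library or either dcr1 deletion library, with log2 fold changes of 1.28 to 1.32, and the TIR1-like segment lost it without wild type replicate 2, with 1.45 to 2.51 over all libraries left out. The unnamed seg13811, at 526 CPM in ago1 deletion replicate 1 and 149 in replicate 2, ranged from 0.83 to 2.65, and seg10176 from 0.65 to 1.63. Both lost their call without either wild type library or either dcr1 deletion library. After the correction for GC content and length, CYT1 (1.11 ± 0.26, adjusted p = 0.127), seg13811 (1.53 ± 0.32, adjusted p = 0.0768), seg10176 (1.16 ± 0.23, adjusted p = 0.0513), seg15343 (−1.85 ± 0.36, adjusted p = 0.0513) and seg03847 (−1.77 ± 0.35, adjusted p = 0.0572) did not pass. DESeq2 called 102 segments, 99 of them rising and 3 falling, and shared 5 with the edgeR calls, while it gave no adjusted p to 21 of the 24 named segments.

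Ribosomal protein segments of the ago1 deletion lay above the wild type as a group. Of 97 segments, 90 had a positive log2 fold change, with a median of 0.49, and camera called the list up (adjusted p = 5.51e-24), but adjusted p = 0.323 with an estimated correlation. Without ago1 deletion replicate 1 the median was 0.24. None passed the test over all segments (0 rose, 0 fell), and 47 rose when adjusted over the list alone. The nearest were RPL18 (seg07747, 0.81 ± 0.17, adjusted p = 0.0554), RPL43 (seg07662, 1.10 ± 0.23, adjusted p = 0.0689) and RPL2 (seg14537, 1.06 ± 0.23, adjusted p = 0.0832). Respiration was called up over 9 segments (adjusted p = 7.8e-05, and adjusted p = 0.323 with an estimated correlation). Its segment seg04544 of CYT1 rose and 8 members did not pass, and 2 rose when adjusted over the list alone. Hexose transporter segments, all matched to HXT1, were called up (25 members, adjusted p = 1.47e-04, and adjusted p = 0.323 with an estimated correlation). Chaperones were called up as well (39 members, adjusted p = 4.46e-04, and adjusted p = 0.376 with an estimated correlation). No member of these last lists rose over all segments, and 1 of each did when adjusted over the list alone. SSB1, a ribosome-bound chaperone, stood at 1.11 ± 0.26 (seg09554, adjusted p = 0.103). Chaperones lost their call without ago1 deletion replicate 1 (adjusted p = 0.629). That library, with its high share of reads made mostly of A (1.88%), had the highest counts for RPL43, RPL2 and SSB1.

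The list of RNA interference genes was called down in the ago1 deletion over 6 segments (adjusted p = 5.74e-05, and adjusted p = 0.323 with an estimated correlation). Its 3 AGO1 segments fell, also when adjusted over the list alone, and the segments of DCR1 and RNT1 did not pass. Lists without a call by camera were glycolysis (53 segments, adjusted p = 0.093), histones (12, adjusted p = 0.093), retrotransposons (11, adjusted p = 0.093), cell wall proteins (10, adjusted p = 0.111), methionine and sulfur genes (3, adjusted p = 0.176) and amino acid synthesis (5, adjusted p = 0.309). The methionine and sulfur segments were all matched to MET17, and the amino acid synthesis segments to LEU2 or HIS3. In every comparison these lists stand for those genes and not for whole pathways. Without ago1 deletion replicate 2, camera called glycolysis up (adjusted p = 1.72e-05) and cell wall proteins up (adjusted p = 0.0201).

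In the dcr1 deletion 39 of 15230 segments rose and 15 fell. Of the 9 named segments with the largest rises beyond the kanamycin marker, 3 resemble Ty3/gypsy retrotransposon proteins. The Ty3/gypsy segment seg01932 (25.6% identity over 234 amino acids) went from 8 and 5 counts in the wild type to 292 and 309 (log2 fold change 5.47 ± 0.28, adjusted p = 1.41e-09), with 7 and 8 counts in the ago1 deletion. The Ty3/gypsy segment seg09636 stood 46.1 times above the wild type (95% interval 12.4 to 386), and seg11924, which carries the opposite strand of such an element, rose by 3.65 ± 0.54. Unnamed segments that rose by the rule were seg02398 (4.06 ± 0.33), seg01918 (3.98 ± 0.23), seg11360 (3.97 ± 0.61), seg16247 (3.63 ± 0.50), seg17098 (20.1 times the wild type, 95% interval 5.22 to 172) and seg10283 (at least 15.0-fold higher, against 3 counts over the group). The CYT1 segment seg04544 rose here too (1.46 ± 0.25, adjusted p = 0.00638), and so did the TIR1-like segment (1.48 ± 0.31, adjusted p = 0.0475). The CYT1 segments seg13637 (1.27 ± 0.50, adjusted p = 0.588) and seg05697 (0.55 ± 0.26, adjusted p = 0.698) did not pass. Of the 38 segments that rose beyond the marker, 26.3% overlapped a segment of the other strand by at least 30 nt at 95% identity or more. Among all tested segments the share was 4.49%, and these shares were looked up after the calls had been seen. The set of 152 segments that overlap by at least 100 nt was not called by camera in the dcr1 deletion (adjusted p = 0.837), with 7 rising. In the ago1 deletion it was not called by camera either (adjusted p = 0.108), but fry called it up (adjusted p = 0.0256).

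**Figure D2:**
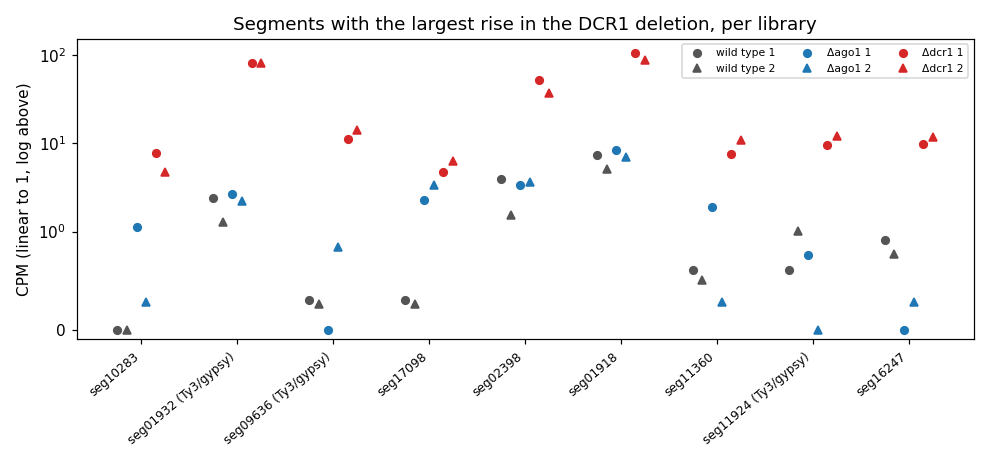
Points show CPM ( linear to 1 and logarithmic above) of each library for the 9 segments with the largest rise in the dcr1 deletion by the naming rule, the kanamycin marker left out. Circles stand for replicate 1 and triangles for replicate 2. For seg01932 the wild type lies at 2.43 and 1.28 CPM and the dcr1 deletion at 81.5 and 81.9 CPM.

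Among the 10 named segments that fell in the dcr1 deletion were seg08980 (at least 15.3-fold lower, against 3 counts over the group), seg05305 (the wild type at 113 times the dcr1 deletion, 95% interval 19.9 to 4509) and seg11028 (−3.12 ± 0.57), which carry no name. Both seg08980 and seg05305 had at most 1 count in each dcr1 deletion library. Whether they are parts of DCR1 was not analysed here. The mitochondrial large ribosomal RNA changed by −1.50 ± 0.19 (seg01629, adjusted p = 2.58e-04) and the small one by −1.36 ± 0.16 (seg00439, adjusted p = 2.19e-04). AT-rich segments that fell were seg04791 (−1.82 ± 0.26), seg02604 (−1.56 ± 0.19) and seg01855 (−1.41 ± 0.18), and seg05800 (−1.25 ± 0.26) and seg03965 (−1.20 ± 0.19) also fell, with 26.0% and 27.2% GC. As a set of 26 chosen after the data had been seen, AT-rich segments were called down in both deletions. In the dcr1 deletion 7 fell (adjusted p = 1.11e-12, and adjusted p = 0.00796 with an estimated correlation), and 7 did when adjusted over the list alone. In the ago1 deletion 3 fell, seg00439 (−0.88 ± 0.16), seg02604 (−1.0 ± 0.19) and seg04285 (−0.98 ± 0.19), and 8 did when adjusted over the list alone (adjusted p = 1.67e-04, and adjusted p = 0.0436 with an estimated correlation). These 3 calls were lost without either wild type library or either dcr1 deletion library. They were also lost after the correction for GC content and length, with −0.47 ± 0.16 (adjusted p = 0.257), −0.52 ± 0.20 (adjusted p = 0.324) and −0.52 ± 0.22 (adjusted p = 0.367) in that order.

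The number of calls in the dcr1 deletion was 23 without wild type replicate 1, 20 without wild type replicate 2, 401 without ago1 deletion replicate 1, 411 without ago1 deletion replicate 2 and 18 without dcr1 deletion replicate 2. Of the 15 named segments that rose, 8 kept their call without any single library, among them seg01932 (5.05 to 5.97), seg09636, seg02398 and seg01918, and 4 of the 10 named segments that fell did, among them both mitochondrial ribosomal RNAs. CYT1 lost its call without either wild type library or dcr1 deletion replicate 2 (1.34 to 1.58), the TIR1-like segment without either wild type or either dcr1 deletion library (1.07 to 1.98), and seg11924 without either wild type library or dcr1 deletion replicate 2 (3.37 to 4.08). After the correction for GC content and length both mitochondrial ribosomal RNAs, seg01629 (−1.16 ± 0.20, adjusted p = 0.0125) and seg00439 (−0.85 ± 0.16, adjusted p = 0.0234), kept their call, and so did seg03965 (−0.98 ± 0.20, adjusted p = 0.0419). Calls lost, with smaller changes, were those of seg01855 (−0.93 ± 0.20, adjusted p = 0.0866), seg02604 (−0.98 ± 0.21, adjusted p = 0.0592), seg04791 (−1.36 ± 0.32, adjusted p = 0.134), seg05800 (−1.01 ± 0.30, adjusted p = 0.429) and the TIR1-like segment (1.22 ± 0.29, adjusted p = 0.134).

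Retrotransposons were called up as a list in the dcr1 deletion (11 segments, adjusted p = 0.00591, and adjusted p = 0.498 with an estimated correlation). Of these, seg01932 and seg09636 rose and 9 did not pass, and when adjusted over the list alone 4 rose and 2 fell. The median of the list was 0.12 and its mean 0.97. The Ty3/gypsy segment seg02190 stood at −0.66 ± 0.22 (adjusted p = 0.489) and the Ty1/copia segment seg03529 at 0.61 ± 0.21 (adjusted p = 0.505). The call was lost without dcr1 deletion replicate 1 (adjusted p = 0.188). Respiration was called up (9 segments, adjusted p = 4.25e-05, and adjusted p = 0.498 with an estimated correlation), with seg04544 of CYT1 rising and 1 rising when adjusted over the list alone. Hexose transporters were called up with no member rising by either adjustment (0 and 0; adjusted p = 2.29e-04, and adjusted p = 0.516 with an estimated correlation), and this call was lost without dcr1 deletion replicate 2 (adjusted p = 0.114).

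Ribosomal proteins were called up in the dcr1 deletion with a median of 0.14 (adjusted p = 6.1e-04, and adjusted p = 0.942 with an estimated correlation), and 1 rose when adjusted over the list alone. RPL18 stood at 0.74 ± 0.17 (seg07747, adjusted p = 0.0847). The call was lost without wild type replicate 2 (adjusted p = 0.735). Lists without a call were chaperones and amino acid synthesis (adjusted p = 0.453 each), methionine and sulfur genes (adjusted p = 0.549), cell wall proteins (adjusted p = 0.568), RNA interference genes (adjusted p = 0.873), glycolysis (adjusted p = 0.876) and histones (adjusted p = 0.908). In the RNA interference list the median was 0.29 and the mean −0.83, since DCR1 (seg17788) was at 0 counts. A segment closest to the alcohol dehydrogenase ADH1 among the proteins searched (seg00615, 78.4% identity over 348 amino acids) was at 0.75 ± 0.17 (adjusted p = 0.0895). Which alcohol dehydrogenase gene it belongs to was not tested. HSP60, the mitochondrial chaperonin, was at 0.61 ± 0.18 (seg00125, adjusted p = 0.362).

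Among 6 repeat families, 2 rose in the dcr1 deletion and 0 in the ago1 deletion by edgeR. Reads of the coding strand of Ty3/gypsy elements rose by 0.62 ± 0.17 on the log2 scale in the dcr1 deletion (adjusted p = 0.00526), with 449 and 596 counts in the wild type, 411 and 469 in the ago1 deletion and 801 and 827 in the dcr1 deletion. Reads opposite to a Y' type helicase, a gene found next to yeast telomeres, rose by 1.20 ± 0.20 (adjusted p = 9.18e-05), from 136 and 158 counts to 282 and 410. This family is a single segment (seg00860, 34.6% identity over 370 amino acids). In the ago1 deletion these families stood at −0.01 ± 0.17 and 0.18 ± 0.21, and the difference between the deletions passed the test for both, with 0.63 ± 0.17 (adjusted p = 0.00478) and 1.02 ± 0.20 (adjusted p = 5.69e-04). In the dcr1 deletion the remaining families did not pass. Ty1/copia stood at 0.13 ± 0.16 on the coding strand and 0.76 ± 0.47 on the opposite strand, the opposite strand of Ty3/gypsy at 0.12 ± 0.17 and the coding strand of the Y' type at 0.07 ± 0.33. By edgeR 0 families reached an unadjusted p under 0.05 in the ago1 deletion, and DESeq2 called 0 there too. The Ty3/gypsy call was lost without wild type replicate 1 (0.55, family count 1), and its rise comes from 2 of its 7 segments, seg01932 and seg09636, since the others did not pass.

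**Figure D3:**
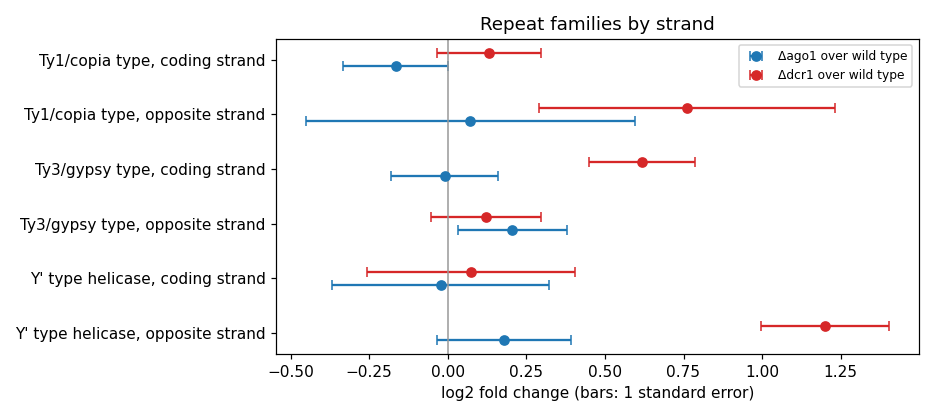
Points show the log2 fold change of each deletion over the wild type for the 6 repeat families by strand, and bars 1 standard error either way. In the dcr1 deletion the coding strand of Ty3/gypsy lies at 0.62 and the opposite strand of the Y' type helicase at 1.20, and in the ago1 deletion at −0.01 and 0.18.

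Antisense reads rose on 8 of 354 segments in the dcr1 deletion and fell on 0. The named ones come in pairs that match each other on opposite strands. The match is at 100% identity for seg04309 with seg03069 and for seg06269 with seg02086, and at 96.3% for seg00123 with seg01918. Whether this last pair is 2 strands of 1 place or diverged copies was not tested. On seg00123 antisense counts went from 6 and 3 in the wild type to 94 and 90 (log2 fold change 4.28 ± 0.49), and on its partner seg01918, with 547 nt of overlap, from 54 and 61 to 235 and 257 (2.06 ± 0.32). The segments seg04309 (2.94 ± 0.39) and seg03069 (2.95 ± 0.41) overlap each other by 349 nt. On seg06269, which overlaps seg02086 by 78 nt, antisense counts were 36 and 38 in the dcr1 deletion and 0 in the other strains, at least 24.2-fold higher than the wild type against 3 counts over the group. Both members of a pair also rose on the sense strand for seg00123 (2.51 ± 0.19) and seg01918 (3.98 ± 0.23), and for seg04309 (3.43 ± 0.30) and seg03069 (2.32 ± 0.24). Sense reads of 1 member can be antisense reads of the other where both match equally well.

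In the ago1 deletion 0 antisense counts passed the test by edgeR and 0 by DESeq2, with 32 of 354 at an unadjusted p under 0.05. The difference of the dcr1 from the ago1 deletion passed for 7 segments, among them seg00123, seg04309, seg06269, seg03069 and seg15599, the last 38.9 times the ago1 deletion level (95% interval 6.64 to 1569). With overlapping segments left out, 34 segments remained, of which 0 were called in the dcr1 deletion by edgeR. The number of antisense calls in the dcr1 deletion was 2 without wild type replicate 1, 0 without wild type replicate 2, 14 without ago1 deletion replicate 1 and 13 without ago1 deletion replicate 2. In the ago1 deletion it was 1 without ago1 deletion replicate 1, 49 without ago1 deletion replicate 2 and 2 without dcr1 deletion replicate 2, and for the difference 25 without ago1 deletion replicate 2.

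The direct comparison of the dcr1 with the ago1 deletion, in which the wild type cancels out, gave 35 segments higher and 9 lower in the dcr1 deletion. Higher were the Ty3/gypsy segment seg01932 (5.06 ± 0.27, adjusted p = 2.68e-09), seg01918 (3.68 ± 0.23, adjusted p = 2.38e-08), seg02086 (2.33 ± 0.18, adjusted p = 5.15e-07) and seg04185 (3.65 ± 0.32, adjusted p = 2.98e-06), and the kanamycin marker (6.37 ± 0.29). Lower were the hygromycin marker, seg05305 (the ago1 deletion at 122 times the dcr1 deletion, 95% interval 21.4 to 4859), seg08980 (at least 16.2-fold), seg10547 (at least 11.8-fold) and seg11476 (at least 9.47-fold), each bound against 3 counts over the group. The place of these unnamed segments relative to DCR1 was not analysed. The AGO1 segments were higher (seg05167 at least 30.7-fold) and DCR1 lower (seg17788 at least 7.89-fold, adjusted p = 0.0353). The DCR1 call was lost without wild type replicate 1 (adjusted p = 0.0887), wild type replicate 2 (0.0993), dcr1 deletion replicate 1 (0.401) and dcr1 deletion replicate 2 (0.503), with reads without mismatch only (adjusted p = 0.0717) and by DESeq2 (adjusted p = 0.11). The retrotransposon list was called higher (adjusted p = 1.36e-06, and adjusted p = 0.142 with an estimated correlation), with 2 rising and 4 rising when adjusted over the list alone. Of the 38 segments that rose over the wild type in the dcr1 deletion beyond the marker, 19 were also called over the ago1 deletion.

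Ribosomal proteins were called lower in the dcr1 than in the ago1 deletion (median −0.36, adjusted p = 6.38e-17, and adjusted p = 0.405 with an estimated correlation), with 0 of 97 passing and 21 falling when adjusted over the list alone. Chaperones (adjusted p = 0.00315, and adjusted p = 0.637 with an estimated correlation) and histones (adjusted p = 0.0435, and adjusted p = 0.405 with an estimated correlation) were called lower, each with 0 members passing by either adjustment. Without ago1 deletion replicate 1 chaperones were higher in the dcr1 deletion instead, without a call (adjusted p = 0.38). The RNA interference list was called higher through its AGO1 segments (adjusted p = 7.52e-07, and adjusted p = 0.158 with an estimated correlation), with 3 rising and 1 falling, also when adjusted over the list alone. The histone call was lost without wild type replicate 1 (adjusted p = 0.0835), wild type replicate 2 (0.085), ago1 deletion replicate 2 (0.179) and dcr1 deletion replicate 2 (0.191). The number of segments that differed was 1344 without ago1 deletion replicate 2, 23 without dcr1 deletion replicate 1 and 24 without dcr1 deletion replicate 2. Of the 8 named segments that were higher, 7 kept their call without any single library, as did 3 of the 6 that were lower.

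On the average of both deletions 20 segments rose and 24 fell against the wild type. They included seg04544 of CYT1 (1.38 ± 0.22, adjusted p = 0.00571), the TIR1-like segment seg10820 (1.74 ± 0.28, adjusted p = 0.00498), seg04694 (1.78 ± 0.34), seg06983 (1.31 ± 0.19), seg02545 (1.28 ± 0.16), seg06026 (1.27 ± 0.17) and seg01283 (1.13 ± 0.19). The segments seg00123 (1.67 ± 0.17) and seg02086 (1.55 ± 0.17) were also called, the second with 58 and 71 counts in the wild type, 61 and 84 in the ago1 deletion and 416 and 448 in the dcr1 deletion. Called as falling were AGO1 and 2 unnamed segments at 0 counts in the ago1 deletion (seg08395 and seg09158), seg15343 (−1.74 ± 0.28) and seg17681 (−1.46 ± 0.30). AT-rich segments that fell were the mitochondrial small ribosomal RNA (−1.12 ± 0.14, adjusted p = 3.97e-04), seg04791 (−1.30 ± 0.21), seg02604 (−1.28 ± 0.16), seg01855 (−1.14 ± 0.15) and seg04285 (−1.08 ± 0.15). None of these passed after the correction for GC content and length, which left −0.66 ± 0.14 for the mitochondrial small ribosomal RNA (adjusted p = 0.0561), −0.84 ± 0.26, −0.75 ± 0.17, −0.68 ± 0.17 and −0.59 ± 0.18 in that order, nor did seg17681 (−1.03 ± 0.31, adjusted p = 0.285). DESeq2 called 32 rising and 16 falling. The count was 21 without wild type replicate 1, 4 without wild type replicate 2, 435 without ago1 deletion replicate 1, 1548 without ago1 deletion replicate 2 and 23 without dcr1 deletion replicate 2. Only 2 of the 10 named segments that rose kept their call without any single library, seg00123 and the kanamycin marker, and 1 of the 11 that fell did, seg05167 of AGO1.

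Of the fixed lists, camera called 5 on the average of both deletions and 0 with an estimated correlation. Respiration (adjusted p = 6.08e-06, and adjusted p = 0.413 with an estimated correlation) had 1 member rising and 3 when adjusted over the list alone, and hexose transport (adjusted p = 1.69e-05, and adjusted p = 0.413) had none by either adjustment (0 and 0). Ribosomal proteins (adjusted p = 7.94e-16, and adjusted p = 0.432 with an estimated correlation) had 1 of 97 rising and 8 when adjusted over the list alone. Chaperones (adjusted p = 0.00933, and adjusted p = 0.545 with an estimated correlation) had 0 by either adjustment. RNA interference genes were called down (adjusted p = 8.48e-04, and adjusted p = 0.413 with an estimated correlation), with 2 falling and 4 falling when adjusted over the list alone. Of the 6 segments of this list, 3 are of AGO1 and 1 is of DCR1, so a fall follows from the deletions themselves. The 2 that fell are of AGO1 (seg05167 and seg07578). The Y' type family on the opposite strand rose (0.69 ± 0.18, adjusted p = 0.00915), a call lost without wild type replicate 1, wild type replicate 2 or dcr1 deletion replicate 2 (0 families each, by edgeR). Antisense counts gave 0 calls by edgeR and 3 by DESeq2, with 35 of 354 at an unadjusted p under 0.05, and by edgeR 9 without ago1 deletion replicate 1, 42 without ago1 deletion replicate 2 and 2 without dcr1 deletion replicate 1.

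Both deletions are compared with the same wild type libraries, which by itself makes their fold changes alike. Called in the same direction in both were seg04544 of CYT1, the TIR1-like segment, seg02545 and seg06026, which rose, and the mitochondrial small ribosomal RNA, seg02604 and seg04285, which fell. The kanamycin segment was also called as rising in both. Its reads in the ago1 deletion fell mostly at positions 801 to 900 (35 and 86 reads), with 0 to 1 in each earlier stretch of 100 positions from 101 on. Its body was hardly covered there, so this call is not a shared rise of the gene. Chance without shared controls would give 0.0359 shared rises and 0.0187 shared falls. Simulations with shared controls made at most 3 calls per comparison, too few to give an overlap. Across segments, which are not independent replicates, the correlation of both fold changes was 0.461, below the simulated mean of 0.487 with shared controls and no change. It was above the simulated maximum without ago1 deletion replicate 1 (0.457 against 0.442) and without dcr1 deletion replicate 1 (0.439 against 0.427). The simulations gave a segment the same spread in all strains. Relative to counting error, the variance between replicates was 1.64 in the wild type and 10.9 in the ago1 deletion. Simulated wild type noise can thus be too large, so a correlation below the simulated mean does not show that a shared response is missing. The covariance of the fold changes was 0.116, above the simulated mean of 0.0768 and the simulated maximum of 0.0838, an excess of 0.0387. The same limit leaves its size uncertain, and the shared controls can still have a part in it. Without wild type replicate 2 the covariance (0.160) was below its simulated mean (an excess of −0.0274), and without wild type replicate 1 it was 0.184, above its simulated maximum of 0.180 (an excess of 0.0167). Without dcr1 deletion replicate 2 the excess was 0.0154.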

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

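The tests of equal action in both deletions and of the strains used, given here, were chosen after the results had been seen, and the test of the difference between the deletions was planned. The dcr1 and ago1 deletions differed in 44 segments by a test of the difference itself. They also differed in the coding strand of the Ty3/gypsy family, by a log2 difference of 0.63, and in the opposite strand of the Y' type helicase family, which is 1 segment, by 1.02, higher in both dcr1 deletion libraries than in both ago1 deletion libraries. Outside the main measurement, reads made mostly of A were 1.88% in ago1 deletion replicate 1 against 0.203% to 0.410% in the other 5 libraries.

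The 38 segments that rose in the dcr1 deletion beyond the marker had a median log2 fold change of 1.91 there, which holds also with the 2 segments absent from the wild type at their lower bound (1.91), and of 0.58 in the ago1 deletion. For loss of RNA interference acting alike in both deletions, the bound set was a median difference under 0.95, and it was 1.41 ± 0.35. This error is taken across segments and is too wide to decide. The segments were also picked for their rise in the dcr1 deletion, which by itself favours a difference. For the 19 of the 38 that the planned test of the difference called over the ago1 deletion, the 2 strains were not alike. Each deletion is represented by 1 strain, so the element content of the strain used cannot be told apart from an effect of losing Dicer, which stays open and untested.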

How the results depend on the processing

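The settings without the segments of AGO1, DCR1 and the markers and with the looser protein match, and the sets of AT-rich and overlapping segments, were chosen after the data had been seen, and all other settings were planned. Of the named segments, 2747 values kept their direction and side of the threshold, 200 lost their call, 109 gained one and 17 changed sign. For family values these numbers were 196, 1, 1 and 18, for list values 330, 34, 6 and 20, and for antisense values 92, 8, 0 and 0. The cause was not tested unless it is given here. The values that changed sign had not passed the test with all libraries, except chaperones in the difference between the deletions.

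The stricter filter on low counts gave 8 changed segments in the ago1 deletion, 27 in the dcr1 deletion, 14 that differed between the deletions and 21 on average. It tested 5691 segments in place of 15230, but calls were also lost on segments it still tested. It raised the correlation of the deletions to 0.537, above its simulated maximum of 0.534. No filter on low counts gave 1 antisense call in the ago1 deletion and 3 on average, and set seg03517 of RNT1 in the ago1 deletion at 0.0012 (−0.0041 before). The replicate block gave 105 changed segments in the ago1 deletion and 89 on average, 2 antisense calls in the ago1 deletion and 4 on average, and turned the overlapping segments in the dcr1 deletion up (adjusted p = 0.921). Under the block 65 segments changed in the dcr1 deletion and 61 differed between the deletions. The samples share only a number, with correlations between libraries of the same number of 0.117, −0.0387 and −0.0479, so the block was not used elsewhere. Sharing reads with several places set seg03517 at 0.0038. Distinct tags gave 57 changed segments in the ago1 deletion and 89 on average. The GC and length correction gave 20 changed segments in the ago1 deletion and set seg09403 of LEU2 in the dcr1 deletion at −0.047 (0.20 before). The GC and length correction with replicate block gave 104 changed segments in the ago1 deletion, 92 that differed and 70 on average, with seg09403 at −0.0459 and seg01504 of LEU2 at −0.0054 in the dcr1 deletion (0.13 before).

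Leaving out the deleted genes and markers gave 18 changed segments in the ago1 deletion, 5 of the calls lost being those segments themselves, and set seg03517 at 0.0105. DESeq2 gave 102 changed segments in the ago1 deletion (99 up, 3 down) and 3 antisense calls on average, with seg03517 at 0.0107, the coding strand of Ty3/gypsy at 0.0085 (−0.01 before) and of the Y' type at 0.0054 (−0.02 before) in the ago1 deletion. Only the 2 groups compared gave 17, 346 and 29 changed segments in the ago1 deletion, the dcr1 deletion and the difference. With overlapping segments left out, the antisense calls were 0 in the dcr1 deletion and 2 in the difference, of 34 tested. Reads without mismatch only put the coding strand of Ty3/gypsy in the ago1 deletion at 0.0226 and of the Y' type at 0.0288. The looser protein match put the opposite strands of Ty1/copia and Ty3/gypsy in the difference at −0.0255 (0.69 before) and 0.113 (−0.08 before), since it added segments to them, and turned the RNA interference list in the dcr1 deletion down (adjusted p = 0.389). With an estimated correlation, 0 of the fixed lists were called in the ago1 deletion, 0 in the dcr1 deletion, 0 in the difference and 0 on average. The AT-rich set, chosen later, kept its call by camera in the ago1 deletion (adjusted p = 0.0436), the dcr1 deletion (0.00796) and on average (0.0139). With fry the numbers of fixed lists called were 1, 1, 3 and 1, and the RNA interference list (adjusted p = 0.289) and the overlapping segments (adjusted p = 0.066) in the dcr1 deletion and amino acid synthesis in the difference (adjusted p = 0.929) changed sign.

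Leaving out 1 library at a time gave 10 to 2057 changed segments in the ago1 deletion, 18 to 411 in the dcr1 deletion, 23 to 1344 in the difference and 4 to 1548 on average. Where an ago1 deletion library was left out, the remaining one was assumed to vary like the other strains, and the distance between the ago1 replicates no longer entered the estimated spread. Antisense calls ranged from 0 to 49 in the ago1 deletion, 0 to 14 in the dcr1 deletion, 5 to 25 in the difference and 0 to 42 on average, and families from 1 to 3 in the dcr1 deletion and 0 to 2 on average. The correlation of both deletions ranged from 0.340 to 0.577 and their covariance from 0.0999 to 0.184. Lists called were 4 to 7 in the ago1 deletion, 3 to 4 in the dcr1 deletion, 4 to 6 in the difference and 4 to 6 on average.

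Values that changed sign without 1 library ranged as follows. In the ago1 deletion these were seg03517 (−0.101 to 0.069), seg07010 of HIS3 (−1.37 to 0.0713), seg09403 (−0.235 to 0.788), the coding strands of the Y' type (−0.344 to 0.296) and Ty3/gypsy (−0.143 to 0.108), and the opposite strands of Ty1/copia (−0.328 to 0.324) and the Y' type (−0.122 to 0.400). In the dcr1 deletion these were seg06664 of HIS3 (−0.0207 to 0.712), seg07606 of LEU2 (−0.132 to 0.521), seg09403 (−0.0359 to 0.458), seg12204 of MET17 (−0.0577 to 0.541), seg01504 (−0.0028 to 0.264) and the coding strand of the Y' type (−0.131 to 0.294). In the difference these were the opposite strands of Ty3/gypsy (−0.204 to 0.0492) and Ty1/copia (−0.0649 to 1.17) and the coding strand of the Y' type (−0.218 to 0.419). Lists that changed direction had these ranges of adjusted p. They were glycolysis (1.72e-05 to 0.381) in the ago1 deletion, and histones (0.727 to 0.898), overlapping segments (0.770 to 0.929), glycolysis (0.312 to 0.735) and RNA interference (0.629 to 0.886) in the dcr1 deletion. In the difference they were amino acid synthesis (0.380 to 0.949), cell wall (0.0432 to 0.439), chaperones (3.04e-08 to 0.380), glycolysis (2.15e-05 to 0.342), respiration (0.126 to 0.737) and hexose transport (0.0322 to 0.987). Glycolysis in the difference was called down without ago1 deletion replicate 2 (adjusted p = 2.15e-05) and up without ago1 deletion replicate 1 (adjusted p = 0.00123), and chaperones turned up without ago1 deletion replicate 1 (adjusted p = 0.380).

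At the depth and 2 libraries per strain used here most small changes would be missed, and depth itself was not varied. Changes of 0.5, 1 and 2 (log2) were planted in simulated counts, each in 66 or 67 segments with a mean of at least 20 counts per library. All strains were given the same spread, and segments with fewer counts are not covered by these shares. Of the planted changes, edgeR called 5.97%, 55.2% and 95.5% in the ago1 deletion (14567 segments tested), 4.48%, 64.2% and 97.0% in the dcr1 deletion (14564 segments), 5.97%, 52.2% and 95.5% in the difference (14496 segments) and 11.9%, 68.7% and 100% on average (14583 segments). False calls made up 4.59%, 7.56%, 4.67% and 7.69% of the simulated calls on segments, in that order of comparisons. For antisense counts (354 segments) a change of 2 was called for 80.3% in each deletion. Not run were the tests of subtelomeric and convergent genes with their other distances, and leaving out antisense genes by distance on the genome, all of which need a genome. Segments overlapping the other strand were left out in place of the last. Repeat families found by matching segments to each other, and planned gene lists with no protein searched, were not run either.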

Other observations

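The tests on segments of 25% to 30% GC and on ribosomal proteins after GC and length correction were set before their results were seen, and those of ribosomal RNA carry-over, of a single library and of the mitochondrial ribosomal RNAs after GC and length correction were chosen after. Among gene groups with under 3 tested segments, URA3 of pyrimidine synthesis (seg01291) stood at 0.69 ± 0.19 in the ago1 deletion and 0.34 ± 0.19 in the dcr1 deletion. NOP1 of ribosome biogenesis (seg01240) stood at 0.58 ± 0.19 and 0.25 ± 0.19. RNR2, which makes DNA precursors (seg00422), stood at −0.13 ± 0.21 and −0.21 ± 0.21, and ERG11 of sterol synthesis (seg00511) at 0.14 ± 0.19 and 0.24 ± 0.19. The Y' type helicase segment seg06888 stood at −0.57 ± 0.37 and −0.39 ± 0.35.

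All 9 unnamed segments that fell to 3 counts or fewer in the ago1 deletion were open over their full length in 1 reading frame, but so were 75.0% of the 10899 short segments tested, and their place relative to AGO1 was not analysed here. The kanamycin marker had 53 and 136 counts in the ago1 deletion. By position along the marker sequence, 35 and 86 reads of the ago1 deletion fell at 801 to 900, where the dcr1 deletion had 540 and 614.

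AT-rich segments, with the mitochondrial ribosomal RNAs among them, fell on the average of both deletions (median −0.26). A general drop in carry-over of RNA without poly(A) tails would lower cytosolic ribosomal RNA too, but its share was higher in every deletion library, with a log2 ratio of 0.30. This share cannot decide on carry-over or content of mitochondrial RNA alone, which were not measured apart. GC content bias would also lower segments of 25% to 30% GC. The 816 such segments had a median of −0.20 ± 0.02, with the error taken across segments, below the bound of −0.13. A bias of GC content is thus a candidate explanation for part of this fall. GC and length correction left the 2 mitochondrial ribosomal RNAs called in the dcr1 deletion and no nearer to 0 than −0.85 ± 0.16 (−1.36 before). The small one lost its call in the ago1 deletion (−0.47 ± 0.16, −0.88 before). The correction was fitted over all 15230 tested segments, of which 26 are in the AT-rich set, so it can correct too little at such low GC. It cannot decide whether the bias is the whole cause, and an effect of losing Dicer on these 2 RNAs stays open.

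Ribosomal protein segments lay above the wild type in the ago1 deletion (median 0.49). After the GC and length correction the median was still 0.42 ± 0.04, so the correction removed little of the shift in these libraries. The errors here are taken across 97 segments and leave out variation between libraries. With an estimated correlation between segments the list was not called (camera, adjusted p = 0.323). Without ago1 deletion replicate 1 the median before the correction was 0.24 ± 0.03 against a bound of 0.25, so whether a single library makes most of the rise cannot be told apart from a rise in both. An effect of losing AGO1 stays open and untested.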
